A study of Arabidopsis thaliana with 4 samples.

How the data were processed

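RNA from whole Arabidopsis thaliana seedlings grown for 4 days in darkness was measured on Affymetrix ATH1 arrays, 2 from wild type (Col-0) and 2 from the ein3-1 eil1-1 mutant, called ein3 eil1 from here on. Genotypes were taken from the labels. The authors deposited 1 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The scaling target, the MAS5 version and detection calls were not given in the sources used here. The medians of the deposited intensities were 49.5 and 52.3 in wild type and 50.8 and 85.2 in the mutant, and the 2% trimmed means ranged from 141 to 249, a spread of 77.2%, so the 4 arrays did not share a common scale. The number of arrays, 2 per genotype, limits the precision of every value.

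The following was computed from the deposited intensities. The table held 22810 probe sets, of which 64 were Affymetrix controls and were left out of the tests. A pseudocount of 3, the 10th percentile of all values, was added before taking log2, so a fold change is on the log2(value + 3) scale and understates the change of dim probe sets. Because the trimmed means differed by more than 5%, the log2 values were quantile normalised between arrays, a rule set before the data were examined. A probe set was tested if it reached its array's 40th percentile on at least 2 of the 4 arrays, which left 14031. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A second count took probe sets that differed by at least 2-fold and whose 2 mutant values lay on the same side of both wild-type values. The order alone, without the 2-fold cut, would be met by 33.3% of unchanged probe sets in either direction.

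Probe sets were named through the platform annotation and RefSeq gene names (assembly TAIR10.1). Of the probe sets, 13513 paired with 1 gene, 503 with several and 8730 were not listed. Of those with 1 gene, 13436 matched a RefSeq gene, and no gene was named from a probe set with several. A gene with several probe sets was represented by the one with the highest mean. Gene lists fixed before the data were examined held 352 entries in 21 lists. Only 46 entries had a named probe set and 38 were tested, so each list describes its named members alone. Lists with at least 3 tested genes were tested with limma's camera (two-sided, preset correlation 0.01), with adjustment over the 5 lists tested. The report names EIN3, for which a named probe set was tested. It also names the 10 genes with the largest fall and the 10 with the largest rise past the threshold, if the higher group's mean reached the array median, filled up by the smallest p values where fewer passed. In the gene lists it names the tested members of both primary lists and, in each other list, those past the threshold or the 2 highest and 2 lowest. EIL1 is not reported here.

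The labels named no batch and numbered no replicates. The Bacillus control probe sets, read after the data had been examined, split the 4 arrays into 2 preparation sets of 1 wild-type and 1 mutant array each. After quantile normalisation the gap between the sets in mean control level was 1.65 log2 units, and the larger gap inside a set was 0.075. In deposited signals the split was the same, but these gaps were 0.94 and 0.82. In all 4 arrays the set followed the titles, which call 1 array of each genotype a biological replicate. An additive block for the preparation set was therefore added as an alternative, and differences within each set are given. Nothing else in the labels pairs the arrays or says whether plants were grown separately, so the p values measure the spread between these samples, which may be partly technical.

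The fit was tested on simulated data for 14031 probe sets, in 10 simulations with 200 changed probe sets each. Without a block, 0.4%, 42.8%, 85.8% and 97.2% of changes of 2-, 4-, 8- and 16-fold were recovered and 0% of the calls were false. With the block, the recovered shares were 50.6%, 97.2%, 98.6% and 99.8%, and 20.5% of the calls were false, between 2.44% and 32.2% in single simulations. The blocked fit has 1 residual degree of freedom per probe set and did not hold its nominal error rate. For a list of 9 genes, camera called 4% of 200 unshifted lists and 100% of lists shifted by 1 log2 unit. The noise was drawn independently for each gene, and the 9 genes were picked at random. The estimated correlation of the chlorophyll and tetrapyrrole biosynthesis list was 0.49, so these shares do not apply to lists of correlated genes.

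Alternatives were other pseudocounts, filters, scalings and variance models, leaving out each array in turn, camera with an estimated correlation, fry and averaged probe sets. Figures were drawn with matplotlib 3.10.9.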

Results

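Expression was measured in whole 4-day-old etiolated seedlings of wild-type Arabidopsis and of the ein3-1 eil1-1 mutant (ein3 eil1), with 2 arrays per genotype. EIN3 and EIL1 are transcription factors of the ethylene pathway. According to the labels, the mutant seedlings accumulate more protochlorophyllide, the chlorophyll precursor that builds up in darkness. The comparison asks which transcripts differ in dark-grown seedlings that lack the function of both genes. Each array held 22810 probe sets, and 14031 were tested. Values are normalised log2 signals, given as mean ± SD, and differences are mutant minus wild type with n = 2 per genotype.

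EIN3 itself was lower in the mutant. Its signal was 9.98 ± 0.36 in wild type and 6.86 ± 0.50 in the mutant, a log2 difference of -3.12 (SE 0.35, limma adjusted p = 0.014, 5.1e-06 with the preparation set as a block and 0.052 without a filter). The difference was -3.22 in preparation set 1 and -3.02 in preparation set 2, where a preparation set is a pair of arrays, 1 of each genotype, that share control levels after normalisation. The part of the transcript that the probe set reads was not compared with the lesion of the allele.

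Of the called probe sets 30 were lower and 11 higher in the mutant, a balance that depended on the setting (36 and 59 under the deposited scaling, 106 and 138 without wild type replicate 1, 55 and 52 without wild type replicate 2). AT5G19250 fell by 6.75 on the log2 scale, from 9.56 ± 0.04 to 2.80 ± 0.93 (adjusted p = 0.0011). AT5G57760 fell by 6.14 (adjusted p = 0.0041), and AT5G19890 fell from 8.55 ± 0.07 to 4.45 ± 0.62 (adjusted p = 0.0041). In these 3 genes the mutant signals lay below the 40th percentile of the array, so the size of the fall depends on the pseudocount. ARL (ARGOS-LIKE), a gene of organ growth and the tested member of the ethylene response list, fell by 3.23, from 9.82 ± 0.55 to 6.59 ± 0.16 (SE 0.34, adjusted p = 0.0097). Its difference was -2.73 in preparation set 1 and -3.73 in set 2. AT2G34020, AT4G11610, AT5G44580, AT2G34700 and AT4G22490 also fell, with log2 differences from -3.75 (AT2G34020) to -2.66 (AT4G22490). Of these 5, the calls of AT2G34020 (adjusted p = 0.10), AT2G34700 (0.0998), AT4G22490 (0.098) and AT5G44580 (0.17) were lost without a filter, and those of AT4G22490 (0.056) and AT5G44580 (0.065) also without a variance trend. The 5 remaining named genes past the threshold were named after their values were seen. They are IAGLU, an auxin glucosyltransferase (-2.49), the thionin gene THI2.2 (-2.49), AT5G50335 (-2.46), EXO, a brassinosteroid-responsive gene (-2.30), and AT5G17700 (-1.82). All 5 calls were lost without a filter (IAGLU 0.18, THI2.2 0.13, AT5G50335 0.23, EXO 0.18, AT5G17700 0.19) and without a variance trend (0.071, 0.056, 0.071, 0.094 and 0.093 in that order). Those of EXO (0.0501) and AT5G17700 (0.55) were also lost under the deposited scaling, that of AT5G50335 without a pseudocount (0.051), and those of AT5G50335 (0.11) and AT5G17700 (0.058) with the stricter filter.

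Of the named genes 6 rose. AT5G37990 rose by 5.68 (SE 0.56, adjusted p = 0.0074), and COR15A, which encodes a cold-induced chloroplast protein, rose by 4.65 (SE 0.54, adjusted p = 0.015). The call of COR15A was lost without ein3 eil1 replicate 1 (4.26, adjusted p = 0.32), without a filter (0.070) and with a stricter filter (0.17), and that of AT5G37990 without ein3 eil1 replicate 2 (5.13, adjusted p = 0.14) and with the stricter filter (0.070). In both, the wild-type signals lay below the 40th percentile of the array (2.19 ± 0.31 and 2.60 ± 0.19), so the size of the rise depends on the pseudocount. IAA29, a member of the Aux/IAA family of auxin-response repressors, rose by 2.32, from 7.56 ± 0.29 to 9.89 ± 0.01 (SE 0.29, adjusted p = 0.023). AT2G16005 rose by 2.82, AT3G21670, a member of the NRT1/PTR transporter family, by 2.67, and AT5G38020 by 2.46 at an adjusted p of 0.0499. All 4 calls, of IAA29 (0.052), AT2G16005 (0.19), AT3G21670 (0.098) and AT5G38020 (0.23), were lost without a filter, and those of AT2G16005 (0.093) and AT5G38020 (0.097) without a variance trend. The call of AT5G38020 was also lost with the larger pseudocount (0.053) and the stricter filter (0.066). AT4G13180 (1.84), AT1G78460 (1.93), AT5G12050 (1.58) and AT1G68570 (1.68) had the next smallest p values and did not pass the threshold, with adjusted p from 0.056 to 0.096. All 4 passed it with the preparation set as a block. Without 1 array in turn, the differences ran from 1.70 to 1.97 for AT4G13180 and from 1.63 to 2.23 for AT1G78460. They ran from 1.47 to 1.68 for AT5G12050 and from 1.60 to 1.77 for AT1G68570. AT4G13180 (limma adjusted p = 0.031), AT1G78460 (0.010) and AT1G68570 (0.047) passed under the deposited scaling. That scaling moved the median of all tested probe sets up by 0.40, which adds to rises by construction. With median centring AT4G13180 and AT1G78460 passed (both 0.032). AT4G13180 also passed with the larger pseudocount (0.0499) and robust variances (0.036).

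**Figure D1:**
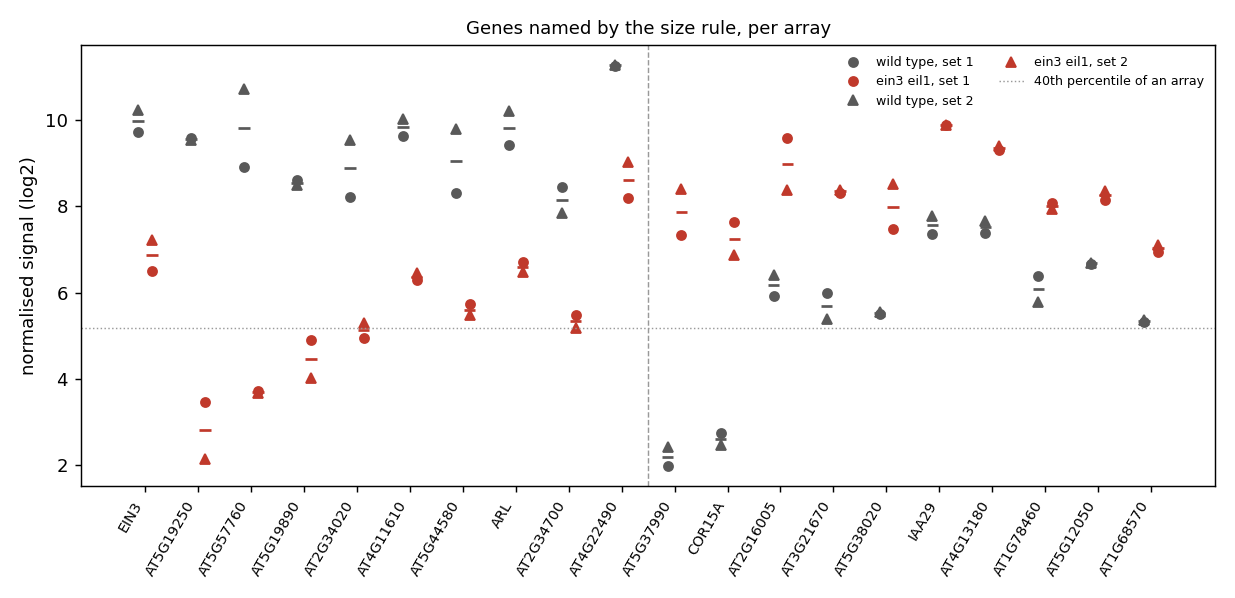
Normalised log2 signal on each of the 4 arrays for the genes named by size, with genes lower in the mutant left of the dashed line and genes higher right of it. Grey marks wild type and red ein3 eil1, circles are preparation set 1 and triangles set 2, and short lines are means. The dotted line is the 40th percentile of an array (5.18), under which both mutant signals of AT5G19250, AT5G57760 and AT5G19890 and both wild-type signals of AT5G37990 and COR15A lie.

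In all, 11 probe sets were higher and 30 lower in the mutant, of which 6 and 15 named 1 gene. All 41 differed in the same direction in both preparation sets, by at least 1.82 log2 units on average, and in 8 of them the lower genotype lay below the 40th percentile of the array. The other 20 calls named no single gene, and the clearest of those differed by -5.05 and -4.72 among the lower and by 3.06 and 2.74 among the higher. By the size rule, 258 probe sets were at least 2-fold higher and 263 at least 2-fold lower. That makes 521, against 608 when the 4 arrays were split by preparation set and 82 when they were split across both. Chance order alone separates 33.3% of unchanged probe sets in either direction. That share leaves out the 2-fold cut, so it is no yardstick for these counts. Within preparation set 1, 341 probe sets were at least 2-fold higher and 435 lower. Within set 2 the numbers were 642 and 468. The sets shared 124 of the higher probe sets, where independent lists would share 15.6, and 159 of the lower, where they would share 14.5.

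With the preparation set as a block, chosen after seeing the data, 177 probe sets were higher and 214 lower, and the 41 were all among them. That fit made 20.5% false calls on simulated data. Under the deposited scaling, 59 were higher and 36 lower, so 37.9% of the calls were lower against 73.2% after quantile normalisation. Leaving out 1 array gave 138 higher and 106 lower without wild type replicate 1, 52 and 55 without wild type replicate 2, 48 and 84 without ein3 eil1 replicate 1, and 65 and 119 without ein3 eil1 replicate 2.

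**Figure D2:**
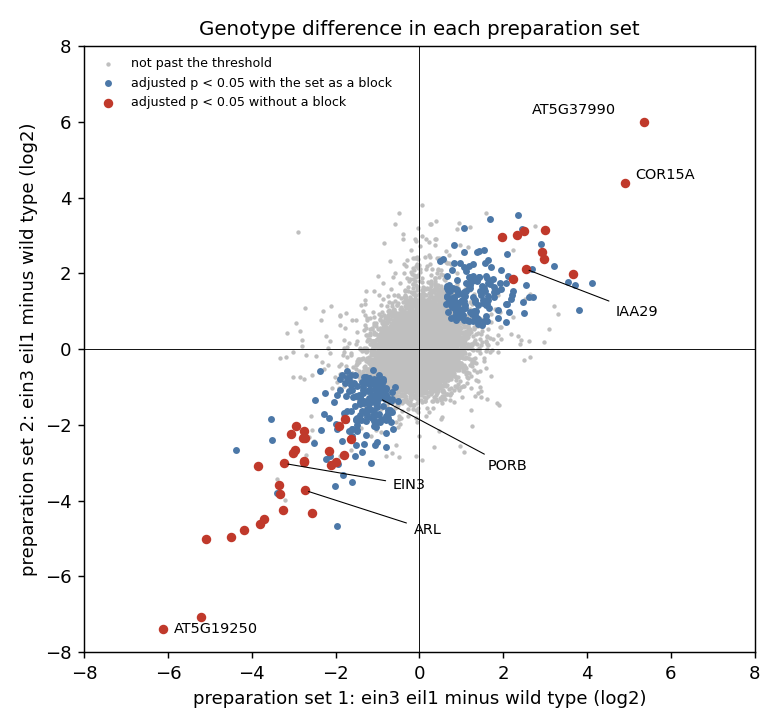
Log2 difference between ein3 eil1 and wild type in preparation set 1 (horizontal axis) and preparation set 2 (vertical axis), with 1 point per tested probe set. Red points passed an adjusted p of 0.05 without a block (41), blue points passed only with the preparation set as a block, and grey points passed neither. Every red point lies at the lower left or the upper right, where both sets have the same sign.

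Genes of chlorophyll and tetrapyrrole biosynthesis had lower means in the mutant, and whether they differ as a group depended on the set test. Of the 31 genes on the list, 9 had a named probe set, and the mutant mean was below the wild-type mean in all 9, with a median log2 difference of -0.48 (camera adjusted p = 1.8e-04). The adjusted p of the list was 0.51 with an estimated correlation and 0.38 with fry. The median was -0.54 in preparation set 1 and -0.35 in set 2. PORB, a light-dependent protochlorophyllide oxidoreductase, had the largest difference, -1.13 (SE 0.33; 12.65 ± 0.62 in wild type against 11.52 ± 0.38), with -0.96 in preparation set 1 and -1.30 in set 2. The magnesium chelatase subunit gene CHLI2 differed by -0.74, and HEME2 and HEME1, for uroporphyrinogen decarboxylase, by -0.56 and -0.52. Without 1 array in turn, CHLI2 ran from -1.42 to -0.07, HEME2 from -1.07 to -0.05 and HEME1 from -0.85 to -0.19. HEMA2 (glutamyl-tRNA reductase) differed by -0.48, CHLP (geranylgeranyl reductase) by -0.46, HEMB1 by -0.43, CHLM by -0.24 and GSA1 by -0.14.

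None of the 9 genes passed the limma threshold alone: 0 passed over all genes, 0 adjusted over the list alone, and 1, PORB, had an unadjusted p under 0.05 (adjusted p = 0.42). With the preparation set as a block, PORB passed (limma adjusted p = 0.0037), and 3 genes passed when adjusted over the list alone. Camera with the block gave an adjusted p of 1.2e-05 for the list (adjusted p = 0.49 with an estimated correlation). Without a block and without 1 array in turn, the difference of PORB ran from -1.57 to -0.69. Without ein3 eil1 replicate 1 the median of the list was -0.19 (adjusted p = 0.14). Under the deposited scaling, which moved the median of all tested probe sets by 0.40, the list median was -0.09, that is -0.49 relative to all probe sets.

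Genes of the photosystems, light harvesting and carbon fixation did not pass the set test as a group. Of 38 genes, 7 were tested, 4 lower and 3 higher, with a median of -0.06 (camera adjusted p = 0.39; 0.55 with an estimated correlation). The medians within the preparation sets were -0.07 and -0.06. LHCB4.2 and LHCB4.1, antenna proteins of photosystem II, differed by 0.14 and 0.12, PRK (phosphoribulokinase) by -0.90 and SBPASE by -0.58. Without 1 array in turn, PRK ran from -1.27 to -0.53 and SBPASE from -1.15 to -0.0059. With limma, 0 passed the threshold over all genes and 0 adjusted over the list alone. Of the 7, 1 had an unadjusted p under 0.05, and 1, PRK, passed with the block (adjusted p = 0.024). With the block the adjusted p of the list was 0.18 with camera, 0.49 with camera at an estimated correlation and 0.025 with fry. The list median was -0.13 without wild type replicate 1 and -0.13 without ein3 eil1 replicate 2. It turned to 0.11 without wild type replicate 2 and 0.10 without ein3 eil1 replicate 1.

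**Figure D3:**
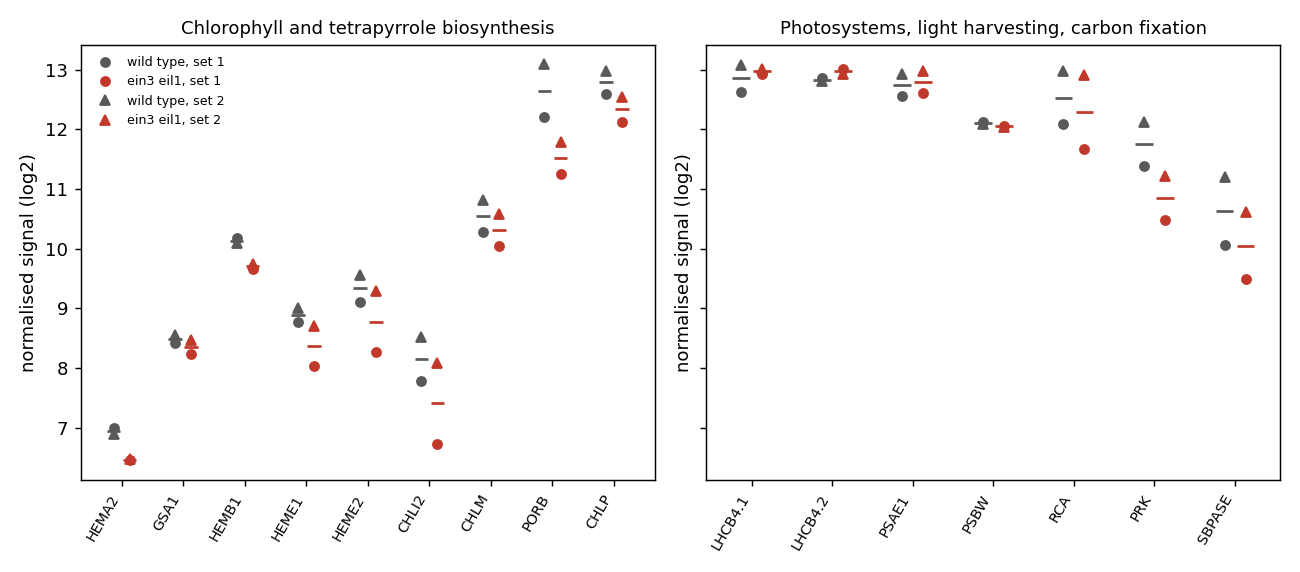
Normalised log2 signal on each array for the 9 tested genes of chlorophyll and tetrapyrrole biosynthesis (left) and the 7 of photosystems, light harvesting and carbon fixation (right). Grey is wild type and red ein3 eil1, circles are preparation set 1 and triangles set 2, and short lines are means. The mutant mean lies below the wild-type mean in all 9 genes on the left and in 4 of 7 on the right.

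Of 22 auxin response and transport genes, 3 were tested, and 1 of them, IAA29, rose. All 3 had positive differences, with a median of 1.60 (camera adjusted p = 1.6e-06). The adjusted p of the list was 0.18 with an estimated correlation and 0.0017 with fry. The medians within the preparation sets were 1.28 and 1.93. Adjusted over the list alone, 2 genes passed. Outside the list, and named after their values were seen, IAGLU fell by 2.49 (adjusted p = 0.035), and IAA20, of the same family as IAA29, differed by -1.95 and did not pass (adjusted p = 0.072, and 5.1e-04 with the block). GH3.3 and GH3.5 encode enzymes that conjugate auxin to amino acids. GH3.3 differed by 1.60 (limma adjusted p = 0.13, and 0.0024 with the block) and GH3.5 by 0.43 (adjusted p = 0.99). Without 1 array in turn, GH3.3 ran from 1.28 to 1.92. With the block the list had a camera adjusted p of 2.6e-06 (0.49 with an estimated correlation) and a fry adjusted p of 0.025.

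The gibberellin and brassinosteroid list and the cell wall list did not pass. Of 17 gibberellin and brassinosteroid genes, the 3 tested were the gibberellin receptor genes GID1A (0.27), GID1C (-0.18) and GID1B (-0.78), with a median of -0.18 (camera adjusted p = 0.51, and 0.31 with the block). The medians within the preparation sets were -0.37 and 0.0034, and without 1 array in turn the median ran from -0.87 to 0.50. With an estimated correlation the camera adjusted p was 0.73. Of 18 expansin and xyloglucan-modifying genes, 5 were tested, with a median of -0.35 (camera adjusted p = 0.34, and 0.21 with the block) and within-set medians of -0.46 and -0.24. EXPA8 differed by 0.76, XTH19 by 0.02, EXPA9 by -0.57 and XTH18 by -1.03. XTH18 passed with the block (adjusted p = 0.030).

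Other lists had too few tested members for a set test. In the ethylene response list, 1 of 22 genes, ARL, was tested, and PDF1.2 was named but too dim. Of 13 ethylene receptor and signalling genes, RTE1, a regulator of the receptor ETR1, differed by -0.98 (adjusted p = 0.42, and 0.034 with the block). Among the light signalling genes FHL, a partner of phytochrome A, differed by 1.02 (adjusted p = 0.44, and 0.042 with the block). The carotenoid genes ZISO (-0.47) and LYC (-0.17) and the oxidative stress genes NODL (-0.44) and ZAT10 (0.31) did not pass in either fit. COR15A was the tested member of the heat, touch and handling stress list.

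Markers of organs and stage were few. The root-expressed gene PYK10 differed by -0.01 (SE 0.19), the reserve mobilisation gene ICL by -0.02 (SE 0.48) and the stomatal lineage gene SPCH by -0.24 (SE 0.61), and all 3 had opposite signs in the preparation sets (-0.04 and 0.01, -0.45 and 0.41, -1.25 and 0.78). The named genes of the root hair list (EXPA7 and EXPA18) and of the flavonoid list (DFR) were too dim to be tested. A further 5 lists, for ethylene biosynthesis, pathogen defence, jasmonate, iron uptake and cell division, had no named probe set here and were not analysed here.

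**Figure D4:**
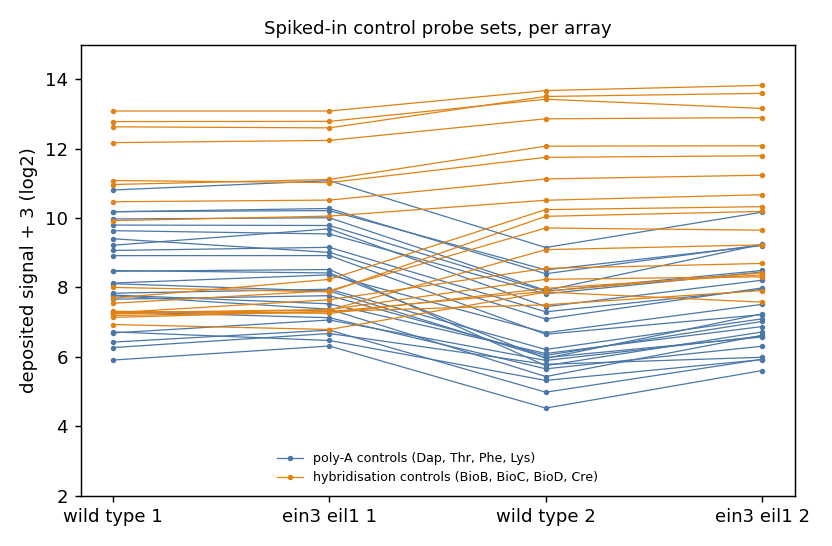
Deposited signal plus 3, on a log2 axis, of the spiked-in control probe sets on the 4 arrays, 1 line per probe set. Blue lines are the 24 Bacillus poly-A control probe sets and orange lines the 18 hybridisation control probe sets. All 24 blue lines are lower and all 18 orange lines higher on both arrays on the right (preparation set 2) than on both on the left (set 1), and each set holds 1 array of each genotype.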

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

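The tests of the labelling batch, RNA integrity and the share of plastid-rich tissue were chosen after the results were seen. The test of the choice of scaling was set before. By its preset rule, a strong shrinkage of the tetrapyrrole median under the deposited scaling or median centring pointed to scaling. That rule was met under the deposited scaling, and the reading as undecided came after.

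Control probe sets outside the comparison carried a signal of their own, and the labels do not say when the control RNAs were added. The 24 Bacillus poly-A control probe sets differed by a median of -1.67 log2 units between preparation set 2 and set 1 in normalised signals, against a median absolute difference of 0.18 inside a set. In deposited signals these values were -1.38 and 0.44. The 18 hybridisation control probe sets were higher in set 2 by a median of 0.56 in normalised signals, against 0.35 inside a set, and by 0.90 in deposited signals, against 0.12. The 25S ribosomal RNA control probe set was 6.02-fold brighter on wild type replicate 2 (6724) than on wild type replicate 1 (1117), with 3051 and 5272 in the mutant.

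The first pattern is that the arrays part by preparation set across genotype. The sets were defined from the Bacillus controls. For the hybridisation controls the difference between sets was 1.60 times that inside a set in normalised signals and 7.49 times in deposited signals. In deposited signals all 24 Bacillus controls were lower and all 18 hybridisation controls higher in set 2, which 1 scale factor per array cannot produce. The levels of the added controls thus differed between the sets. Whether a labelling or hybridisation batch also moved the plant transcripts stays open, because the ratio depends on the scaling. The mean 3' to 5' log2 ratio of actin and GAPDH differed by -0.23 between the sets, with up to 0.18 inside a set. For an actin probe-set pair the log2 ratio was 4.18 on wild type replicate 1 and 3.45 on wild type replicate 2. That ratio changed less between the mutant arrays, and the other ratios changed less in both genotypes. A difference in RNA integrity between the sets stays open, because the mean covers ratios that moved by unequal amounts. The sets also carry the titles' biological replicates, so growth or harvest may differ between them, and no biological explanation was tested. Each set holds both genotypes, so an additive difference between the sets cancels in the genotype difference within each.

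The second pattern is that the 9 tested tetrapyrrole genes had lower means in the mutant. The 67 plastid-encoded genes had a median of -0.01 (SD over genes 0.22), and the tetrapyrrole median lay -0.47 from it (95% bootstrap interval over genes -0.69 to -0.23). This difference was -0.57 and -0.21 within the preparation sets, -0.28 without wild type replicate 1 and -0.22 without ein3 eil1 replicate 1. The difference from the 7 photosynthesis genes, -0.42, had an interval from -0.68 to 0.12. On these arrays the tetrapyrrole median thus lay below the plastid-encoded one in both sets. Both intervals resample genes and hold no spread between arrays, so a smaller share of plastid-rich tissue stays open. Under the deposited scaling the list median was 0.195 of its value, but that scaling moved the median of all tested probe sets by 0.40, so the shrinkage was fixed by construction and decides nothing. Camera passed there (adjusted p = 0.0028) and with median centring (-0.50, adjusted p = 3.2e-04). Median centring shifts every probe set of an array equally, so both scalings left the list at -0.49 relative to all probe sets. Camera compares a list with the other genes, so these passes decide nothing about scaling. With an estimated correlation and quantile normalisation the camera adjusted p was 0.51. Whether the genes lie lower in absolute terms cannot be told apart from the choice of scaling, and an effect of genotype on them stays open, as untested beyond this comparison.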

How the results depend on the processing

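The block for the preparation set was chosen after seeing the data, and the other alternatives were set before. The pairs of arrays in that block were read from control levels, and in all 4 arrays they follow the titles. The 41 calls kept their sign under every setting in which they were fitted. Of them, 39 remained without a pseudocount, 40 with the larger one, 14 without a filter, 24 without a variance trend, 29 with the stricter filter, 37 under the deposited scaling and 41 with median centring, robust variances or the block, and 40 or 41 without 1 array. Without a filter, 2 probe sets were higher and 12 lower, 880 and 896 differed by at least 2-fold, and the ethylene response median was -1.92, because PDF1.2 entered beside ARL. With the stricter filter, which tests fewer probe sets, 6 were higher, and 134 and 163 were at least 2-fold higher and lower. Under the deposited scaling 59 were higher, and 792 and 131 were at least 2-fold higher and lower, with the median of all probe sets at 0.40. With median centring 17 were higher. With the block 177 were higher and 214 lower.

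Leaving out 1 array, where the lone array is assumed to vary like the other genotype, gave 48 to 138 higher and 55 to 119 lower, 336 to 678 at least 2-fold higher and 311 to 541 at least 2-fold lower. These fits have 1 residual degree of freedom, as the blocked fit does, and were not simulated, so passing in them carries little weight. The tetrapyrrole median ranged from -0.67 to -0.19, and the cause was not tested. Its value of -0.48 lost the threshold with an estimated correlation (adjusted p = 0.51) and with fry (adjusted p = 0.38). Of its 14 alternatives 11 passed, and all 11 used camera with the preset correlation of 0.01. The call thus rests on that preset. The list's own correlation was 0.49, estimated without a block on 2 residual degrees of freedom. The auxin list, at -0.33, also lost the threshold with an estimated correlation (camera adjusted p = 0.18). The loss thus cannot be put down to the size of the correlation alone. PORB passed in 3 of 13 alternatives (adjusted p from 0.0023 to 0.89), EIN3 and IAA29 in 12 of 13 (0.052 without a filter), ARL in 13 of 13 and COR15A in 10 of 13.

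Signs that turned belonged to genes and lists not past the threshold. Under the deposited scaling, which moves all genes up, GSA1 was at 0.28, CHLM 0.16, PSBW 0.37, RCA 0.073, LYC 0.25, GID1C 0.14, EXPA4 0.035, ICL 0.42, PYK10 0.28 and SPCH 0.079. The medians of the photosystem, gibberellin and brassinosteroid, and cell wall lists were then 0.37, 0.14 and 0.035. With median centring PSAE1 was at -0.021 and ICL at 0.011. Without 1 array, values ran from -0.51 to 0.036 for CHLM, -0.051 to 0.59 for GID1A, -0.87 to 0.50 for GID1C, -0.79 to 0.76 for ICL, -0.11 to 0.35 for LHCB4.1, -1.06 to 0.18 for NODL, -0.13 to 0.25 for PSAE1, -0.14 to 0.12 for PYK10, -0.87 to 0.38 for RCA, -0.89 to 0.41 for SPCH, -0.19 to 0.22 for XTH19 and -0.16 to 0.79 for ZAT10. The gibberellin and brassinosteroid median then ran from -0.87 to 0.50 and the photosystem median from -0.13 to 0.11. Apart from the deposited scaling's construction, the cause was not tested. Over the named genes and the lists other than the 2 primary ones, 46 values crossed the threshold to pass, 36 no longer passed and 40 turned sign, out of 884 refits. With 2 arrays per genotype and no detection calls, signals near the floor limit what can be told of dim genes.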

Other observations

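All tests here were chosen after the results were seen.

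Of 13 gene groups, 3 had higher medians in the mutant and passed a test that assumes a small correlation between genes. The 6 tested genes of the NRT1/PTR family had a median log2 difference of 0.30 (camera adjusted p = 0.0026 over the 13 groups, and 0.0040 with the block), and 29 UDP-glycosyltransferase genes a median of 0.36 (adjusted p = 0.011, and 0.013 with the block). The 10 beta-glucosidase genes had a median of 0.21 (adjusted p = 0.0497, and 0.068 with the block). With an estimated correlation the camera adjusted p was 0.44 for all 3. The XTH and GH9 families, which did not pass with the small correlation, had the same 0.44. That test thus does not tell the groups apart, and whether correlation between genes accounts for the 3 passes stays open. Within preparation sets 1 and 2 the medians were 0.28 and 0.33 for NRT1/PTR, 0.080 and 0.52 for UDP-glycosyltransferases, and 0.23 and 0.18 for beta-glucosidases. The medians of these 3 were 0.69, 0.73 and 0.61 under the deposited scaling, where all probe sets moved by 0.40, and with median centring 0.29, 0.32 and 0.21. The XTH and GH9 families had medians of -0.27 (adjusted p = 0.079) and -0.25 (adjusted p = 0.19), which were 0.071 and 0.11 under the deposited scaling and -0.33 and -0.30 with median centring. Within sets 1 and 2 they were -0.11 and -0.33 for XTH, and -0.38 and 0.066 for GH9, which changed sign. The 10 genes of the EXP family went the other way, with a median of 0.32 (camera adjusted p = 0.19) and 0.16 and 0.39 within sets 1 and 2. It was 0.73 under the deposited scaling and 0.33 with median centring. The 67 plastid-encoded genes had a median of -0.01 (adjusted p = 0.44), which was 0.34 under the deposited scaling and -0.06 with median centring, and 0.031 and -0.14 within sets 1 and 2.

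LIL3:1 and LIL3:2, light-harvesting-like proteins linked to chlorophyll synthesis, differed by -0.99 and -0.91, and passed with the block alone (adjusted p = 0.038 and 0.028; 0.72 and 0.38 without it). COR15B, a relative of COR15A, differed by 1.64 (adjusted p = 0.28, and 0.028 with the block), with wild-type signals below the 40th percentile. IAA20, of the same family as IAA29, differed by -1.95 (limma adjusted p = 0.072, and 5.1e-04 with the block), and passed with median centring (-1.95, adjusted p = 0.035). Without 1 array in turn its difference ran from -2.33 to -1.57. These 4 genes were named after their values were seen.

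Among genes that passed with the block, neighbours shared a direction more often than in shuffled calls. Of 7334 named genes in chromosome order, 191 passed with the block, and 9 neighbouring pairs shared a direction, against a mean of 2.47 and a maximum of 12 in 10000 shuffles (permutation p = 0.0011). Only 1 of the 9 pairs, AT5G37990 with AT5G38020, had both genes past the threshold without a block, and in the other 8 at least 1 gene was not past it: beside COR15A, COR15B had an adjusted p of 0.28, and beside IAA29, AT4G32290 had 0.45. For the 21 genes called without a block, that 1 pair compares with a mean of 0.031 and a maximum of 2 in shuffles (permutation p = 0.031), which rests on a single pair. Runs of neighbours that respond together are a candidate explanation, and similar sequences in neighbouring gene copies could give the same count, which was not tested. The calls behind the pairs come from the blocked fit, which made 20.5% false calls on simulated data.

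A chromosome segment of another strain carried along with either mutation might also change genes near EIN3 and EIL1. Of 400 named genes nearest to both loci, 14 passed with the block, against 176 of 6933 elsewhere. The odds ratio was 1.39 (exact 95% interval 0.74 to 2.43), and the width of the interval keeps this open.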
